A study of Mus musculus with 12 samples.

How the data were processed

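RNA of splenic B cells from wild type and EFLmDREAM transgenic mice was measured on single-channel Affymetrix mouse genome arrays from 4 µg of total RNA. B cells had been isolated by depletion of CD43-positive cells, with a stated purity above 98%. The cells were unstimulated (day 0) or had been kept for 2 days with LPS at 20 µg/ml and IL-4 at 10 ng/ml. Each of the 4 groups held 3 independent replicates, 12 arrays in all.

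The deposited values are log2 probe set summaries, made with RMA from the affy package per the submitters' processing notes, which give no versions. That scale was checked on the values: the columns have 2 decimals, are positive throughout, and have medians of 5.97 to 6.05 in unstimulated and 5.36 to 5.41 in stimulated arrays. The root mean square distance between the sorted values of 2 arrays was 0.014 to 0.070 among unstimulated arrays, 0.014 to 0.039 among stimulated arrays and 0.449 to 0.507 between the states. Values are not centred per gene and a higher value is a brighter probe set. Whether the arrays were normalized in 1 set or by state is not given in the sources used here. RMA's quantile normalization gives all arrays of 1 run near-equal distributions, so the distances between the states argue against 1 such run.

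Of 45101 probe sets, 64 array controls were left out and 45037 tested. A single gene symbol was given for 34945 of them, 932 carried several symbols and 9160 none; of the first, 34741 also matched by Entrez identifier. For statements about genes, the probe set with the highest mean over the 12 arrays stood for each of 18193 genes, among probe sets of that gene alone. The array annotation names no genome build; gene order was taken from a RefSeq table of GRCm38.p6.

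Groups were compared with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 12 arrays, no block, and the moderated test with a constant prior (8 residual and 4.71 prior degrees of freedom). Tests are 2-sided unless stated otherwise. The p-values of probe sets were adjusted by Benjamini and Hochberg over the 45037 probe sets, and an adjusted p under 0.05 was called. The 5 contrasts were transgenic against wild type in each state, stimulated against unstimulated in each genotype, and the interaction. A further fit of the same model to quantile-normalized values gives the stimulation changes. The comparisons, their tests, the gene lists and the alternatives were fixed before the data were examined. The use of quantile-normalized values for the stimulation changes was chosen after the array medians were seen, and most tests of technical explanations after the results they address.

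Whether replicates with the same number resemble each other was checked by correlating their deviations from the group means between the compared groups. For the stimulated genotypes r was 0.33, 0.10 and 0.18 for replicates 1, 2 and 3, each above the highest value with another number (−0.12, 0.045 and 0.057), and for wild type stimulation it was 0.32, 0.18 and 0.19 (others −0.18, 0.098 and 0.085). The Y-linked Eif2s3y read 3.33 to 3.78 in replicate 3 of every group and 8.27 to 9.55 in the other arrays, so the number also tracks this marker. The labels state independent replicates and name no pairing across groups, which they do not exclude. The unblocked model was kept and the block is an alternative.

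The genes named are Kcnip3, the 10 largest rises and 10 largest falls per contrast among called genes whose groups do not overlap (5 and 5 for the interaction, without the overlap rule), up to 4 called members with the largest change of each list, and a fixed set of B cell genes; clones and predicted genes were skipped. The 34 lists, written from general knowledge, cover the KChIP family, candidate DREAM targets, immunoglobulin constant regions, the plasma cell programme, class switching and germinal centre, B cell identity and receptor signalling, quiescence, mitosis (G2/M), DNA replication (S phase), cyclins D and CDK inhibitors, the IL-4, NF-kB and TLR4, interferon and unfolded protein responses, immediate early genes, ribosome biogenesis and MYC targets (1 list), glycolysis, cholesterol synthesis, oxidative phosphorylation, MHC class II, calcium signalling, apoptosis, the KLF and SP family, markers of marginal zone, follicular, transitional and B-1 cells, of T and NK cells, myeloid cells, granulocytes, erythroid cells, platelets and stromal cells, and sex-linked genes. Lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, adjusted over 170 tests of 34 lists in 5 contrasts. List members with no probe set of their own were not analysed here.

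The procedure was tested on simulated data with the spread of the 12 arrays, in which 200 of 45037 probe sets were changed. It recovered 53.7% of changes of 0.5 on the log2 scale, 92.5% of changes of 1 and all changes of 2, with 13 false among its calls beside 164 true ones. A list shifted by 0.5 between the unstimulated genotypes was recovered (adjusted p = 2.04e-32), with 2 other calls in 170 tests. Such a shift also enters the interaction, so these 2 calls need not be false. They give no rate of false list calls for the real arrays, where members of some lists vary together. Correlations estimated within lists ran from −0.074 for platelet markers to 0.44 for mitotic genes. With the real arrays regrouped in both states, up to 23 list tests passed. Those groups kept most of their arrays in place, so this number is no rate of false calls either. Permutation p-values used 100000 random draws.

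Alternatives were a filter on dim probe sets, quantile normalization, subtraction of array medians, a trended and robust prior, a fit of only the groups compared, array weights, a replicate block, 1 brightest probe set or the mean of probe sets per gene, a minimum change of 1 on the log2 scale, each array left out in turn, and for lists an estimated correlation and limma's fry. Other splits of the arrays were also fitted. Scanner files were not used here.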

Results

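Transcript levels were measured on Affymetrix mouse genome arrays in splenic B cells of wild type mice and of transgenic mice carrying EFLmDREAM, a transgene of DREAM. DREAM is the calcium-binding protein encoded by Kcnip3, a member of the KChIP family of calcium sensors that also binds DNA as a transcriptional repressor. Cells were taken unstimulated or after 2 days with lipopolysaccharide (LPS), which activates B cells through TLR4, and interleukin 4 (IL-4), which directs class switching. The 4 groups held 3 arrays each, 12 in all, and the number of arrays limits the precision. The array medians lay between 5.97 and 6.05 on the log2 scale in the 6 unstimulated arrays and between 5.36 and 5.41 in the 6 stimulated arrays. Correlations between arrays of a group ran from 0.984 to 0.997, and between arrays of different states from 0.898 to 0.915. Changes are log2 differences ± SE from limma, with n = 3 arrays per group, and levels are means ± SD.

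**Figure D1:**
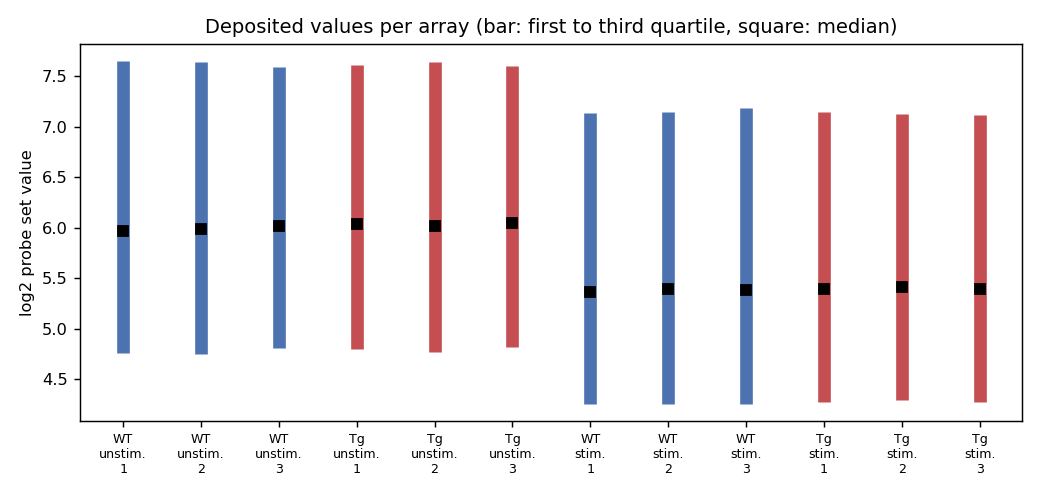
Deposited log2 probe set values of the 12 arrays, with the lower to upper quartile as a bar and the median as a square. The unstimulated medians lay between 5.97 and 6.05 and the stimulated medians between 5.36 and 5.41.

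Kcnip3, the gene behind the transgene, was compared first. Its brighter probe set differed by 0.23 ± 0.12 between transgenic and wild type unstimulated cells (adjusted p = 0.279) and by 0.030 ± 0.12 between the stimulated groups (adjusted p = 0.976). Levels of Kcnip3 were 6.88 ± 0.27 in wild type and 7.12 ± 0.15 in transgenic unstimulated cells, and 6.60 ± 0.059 and 6.63 ± 0.13 after stimulation. The other Kcnip3 probe set differed by 0.10 ± 0.10 and by 0.020 ± 0.10, with adjusted p = 0.612 and adjusted p = 0.98. Whether either probe set reads the transgene's transcript is not given in the sources used here, so these values do not check the genotype labels. None of the 4 KChIP family members passed the test by genotype in either state.

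The comparison of unstimulated transgenic with unstimulated wild type cells asked which transcripts differed before activation. The largest rises in transgenic cells were in antimicrobial genes of neutrophils: S100a9 and S100a8, which encode the calcium-binding proteins of calprotectin, were higher by 4.89 ± 0.19 and 4.62 ± 0.18 (29.7-fold and 24.6-fold, adjusted p = 8.2e-09 and 8.49e-09). Complement C1q genes of macrophages, such as C1qa (2.58 ± 0.11), and erythroid genes, such as the red cell ammonium channel Rhag (2.47 ± 0.22), were higher as well. Genes of the plasma cell programme and markers of marginal zone B cells, the blood-facing B cells of the spleen, were higher in the same samples. Whether RNA of cells other than B cells added to the rises of the plasma cell and marginal zone genes was not tested. The largest fall was in Mndal, an interferon-inducible gene, which changed by −6.86 ± 0.19: its level was 12.79 ± 0.25 in wild type and 5.94 ± 0.049 in transgenic cells.

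In unstimulated cells 12 of 15 measured granulocyte markers were higher in transgenic cells and none was lower, 13 adjusted over the list alone, with a median change of 2.62 (camera adjusted p = 4.34e-25). They included Ngp (4.03 ± 0.17), a neutrophil granule protein, Lcn2 (3.60 ± 0.25), which binds bacterial siderophores, Camp (3.36), the cathelicidin, and Ltf (3.23), lactoferrin. Among the markers of monocytes, macrophages and dendritic cells 15 of 21 were higher, 16 adjusted over the list alone, among them C1qb (2.49 ± 0.11), C1qc (1.78 ± 0.13) and Cd14 (1.91 ± 0.20), the co-receptor of TLR4 (median 1.05, adjusted p = 1.19e-17). Erythroid markers were higher in 8 of 12 cases, 10 adjusted over the list alone, led by Rhag, Alas2 (2.18 ± 0.22), the heme synthesis enzyme of red cells, and Slc4a1 (2.06 ± 0.26), the anion exchanger (median 1.28, adjusted p = 1.01e-11). The iron exporter Slc40a1 (2.91 ± 0.16), the interleukin gene Il1b (2.85 ± 0.22), Chil3 (3.16 ± 0.39), a chitinase-like protein of myeloid cells, and Ctse (3.84 ± 0.089), cathepsin E, completed the 10 largest rises. In wild type unstimulated cells 8 of the 15 granulocyte, 15 of the 21 myeloid and 8 of the 12 erythroid markers already lay above the mean array median of 5.99, and 2 of the myeloid and 1 of the erythroid markers stand in another list. The B cells had been isolated by removing CD43-positive cells, with a stated purity above 98%.

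Markers of T and NK cells were higher in 5 of 17 cases, 7 adjusted over the list alone, with a median of 0.32. For T and NK cell markers camera gave adjusted p = 2.52e-05, and adjusted p = 0.114 with an estimated correlation. The 4 with the largest change were cytotoxic genes or genes of NK cells: Gzma (1.45 ± 0.18), Klrd1 (1.13 ± 0.18), Ccl5 (0.95 ± 0.12) and Nkg7 (0.88 ± 0.11). Of 9 platelet markers 2 were higher, and 3 adjusted over the list alone. For platelet markers camera gave adjusted p = 0.0359, and adjusted p = 0.119 with an estimated correlation. That list's call was lost without wild type replicate 1 (adjusted p = 0.0507), wild type replicate 3 (adjusted p = 0.0676) or transgenic replicate 2 (adjusted p = 0.0936), and after quantile normalization (adjusted p = 0.0681). The stromal and endothelial list held 1 higher gene of 15, and did not pass (adjusted p = 0.656). Wild type unstimulated replicate 1 stood apart in RNA quality: the difference of its actin probe sets, 5′ minus 3′ end, was −2.22, against −0.67 to −0.54 in the other 5 unstimulated arrays. Without that array the 3 leading lists kept adjusted p = 6.66e-26 for granulocyte, 1.07e-17 for myeloid and 2.15e-11 for erythroid markers.

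Of 18 measured genes of the plasma cell programme, 12 were higher in unstimulated transgenic cells and none was lower, 13 higher adjusted over the list alone (median 0.55, adjusted p = 1.01e-10). They included Prg2 (2.14 ± 0.28), which is also a granule protein of eosinophils, Tent5c (0.84 ± 0.14), the endoplasmic reticulum protein Derl3 (0.81 ± 0.086) and the transcription factor Xbp1 (0.75 ± 0.086), while Prdm1, which encodes BLIMP-1, read 0.27 ± 0.15 and did not pass (adjusted p = 0.29). Igha, the constant region of IgA, was higher by 1.33 ± 0.11 at its brightest probe set and at all 3 of its probe sets. The immunoglobulin list of 3 measured genes did not pass (adjusted p = 0.216), nor did Ighg3 (−0.61 ± 0.24). Ighm read 0.12 ± 0.067 at its brightest probe set, and of its 11 probe sets 2 were higher and 3 lower. In the unfolded protein response list, which shares 5 genes with other lists, 10 of 23 were higher, among them Pdia4 (0.70 ± 0.12), Edem1 (0.65 ± 0.093) and Creld2 (0.53 ± 0.091), and 1 was lower; 12 and 1 adjusted over the list alone. For the unfolded protein response camera gave adjusted p = 4.94e-06, and adjusted p = 0.0686 with an estimated correlation.

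Marginal zone B cell markers were higher in 12 of 16 cases, also adjusted over the list alone, and lower in none (median 0.48, adjusted p = 2.38e-10). The largest changes were in Asb2 (1.26 ± 0.10), the tetraspanin Cd9 (1.16 ± 0.15), Cd1d1 (0.82 ± 0.12), which presents lipids, and Marcks (0.79 ± 0.11); all 16 members lay above the array median in wild type cells. Of 11 follicular markers 3 were lower, led by Cd55 (−0.57 ± 0.071), and 1 was higher, or 5 and 1 adjusted over the list alone. For follicular markers camera gave adjusted p = 0.0285, and adjusted p = 0.253 with an estimated correlation. The follicular call was lost without wild type replicate 3 (adjusted p = 0.27) or transgenic replicate 3 (adjusted p = 0.0521). Among 13 B-1 cell markers 5 were higher, including Itgam (1.13 ± 0.17), which is also a myeloid marker, Anxa2 (0.97 ± 0.13) and the galectin Lgals1 (0.85 ± 0.087), and 6 higher with 1 lower adjusted over the list alone. For B-1 markers camera gave adjusted p = 9.08e-05, and adjusted p = 0.0821 with an estimated correlation. The list of transitional B cell markers (adjusted p = 0.862) and the 26 genes of B cell identity and receptor signalling (2 higher, 3 lower, adjusted p = 0.21) did not pass; the latter passed as lower without wild type replicate 1 (adjusted p = 0.0403).

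Genes of class switching and the germinal centre were lower in 6 of 19 cases, 8 adjusted over the list alone, and higher in none. For class switching genes camera gave adjusted p = 7.95e-05, and adjusted p = 0.172 with an estimated correlation. The largest changes were in Rif1 (−0.82 ± 0.11) and Trp53bp1 (−0.74 ± 0.13), which with Msh6 (−0.58 ± 0.12) act in the repair of DNA breaks or mismatches. Immediate early genes were higher in 4 of 22 cases, 6 adjusted over the list alone, with Ier3 (0.84 ± 0.10) and Egr1 (0.62 ± 0.14) in front. For immediate early genes camera gave adjusted p = 0.000824, and adjusted p = 0.0754 with an estimated correlation. Of 29 candidate DREAM targets, collected from general knowledge of the protein, 3 were higher, among them Egr1 and the sodium-calcium exchanger Slc8a1 (0.41 ± 0.081), and 2 were lower, and the list did not pass (adjusted p = 0.254). Egr1 changed by 0.54 without transgenic replicate 1 and was then not called. Klf9, another candidate target, had 7 probe sets, of which 1 was higher and 2 lower. The higher probe set (0.49) had a mean of 5.46 in wild type cells, and the lower ones (−0.33 and −0.56) had means of 8.93 and 8.89. In stimulated cells 1 of the 7 was lower in transgenic cells (−0.71) and 0 were higher. Mitotic genes were higher in 4 of 29 cases, led by Ube2c (0.78 ± 0.12), 7 adjusted over the list alone. For mitotic genes camera gave adjusted p = 0.00471, and adjusted p = 0.533 with an estimated correlation. The mitotic call was lost without wild type replicate 3 (adjusted p = 0.337). The interferon list passed with 2 higher, led by Rsad2 (1.30 ± 0.15), and 1 lower, Gbp2 (−0.60 ± 0.11), of 20. For interferon genes camera gave adjusted p = 0.0285, and adjusted p = 0.578 with an estimated correlation. The interferon list lost its call without wild type replicate 3 (adjusted p = 0.241) or transgenic replicate 1 (adjusted p = 0.304).

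The 10 largest falls in unstimulated transgenic cells were mostly called at 1 probe set each. Slc15a2 (−4.89 ± 0.27), a peptide transporter, fell at 1 of 3 probe sets, and Ifi213 (−3.58 ± 0.20), Mdm1 (−2.63 ± 0.12), Plk2 (−2.01 ± 0.083), Col6a4 (−1.94) and Golt1b (−1.74) each fell at 1 of 2. The pattern-recognition receptor Tlr1 (−2.60 ± 0.10) and Crisp3 (−2.26 ± 0.10) have 1 probe set each. H2-K1, a class I antigen-presenting molecule, fell by 2.12 on the log2 scale at its brightest of 4 probe sets and at 1 other (−3.69). H2-D1, H2-Aa and Parp1 were named after their values were seen. H2-D1 was higher at 3 of its 9 probe sets, by at most 0.77, and lower at 4, down to −4.82. H2-Aa and Parp1 each fell at 1 of 4 probe sets (−3.28 for each). A change in the level of the whole transcript would move all probe sets of a gene the same way. The opposite calls of H2-D1, again 3 higher and 4 lower in stimulated cells, argue against such a change alone. So do the other Parp1 probe sets, at 0.087, −0.12 and −0.33 and none called. Whether sequence differences caused this was not tested. For the other genes, sequence differences under single probe sets cannot be told apart from changes in the transcript. Among cyclins and inhibitors of cyclin-dependent kinases 5 of 16 were higher, including Cdkn1a (0.87 ± 0.12), Ccnd2 (0.76 ± 0.080) and Ccnd1 (0.62 ± 0.10), and 1 was lower (adjusted p = 0.0703, and 0.0378 after quantile normalization).

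Over all 45037 probe sets, 4256 passed limma's moderated test between the unstimulated genotypes, 2013 higher and 2243 lower in transgenic cells, and 517 of them changed at least 2-fold (338 higher, 179 lower). With each array's median subtracted, 4269 passed, 1550 higher and 2719 lower. Counted as genes, 992 were higher and 892 lower of 18193, and the arrays of the genotypes did not overlap for 25.4% of the genes, against 10% by chance. The count was 2611 without transgenic replicate 1, 2174 without transgenic replicate 3 and 7518 without wild type replicate 3, and it was 1908 when only these 6 arrays were fitted. Of 34 lists, 12 passed as higher and 2 as lower; 5 calls held with an estimated correlation, those of granulocyte (adjusted p = 0.0113), myeloid (0.0233), erythroid (0.046), plasma cell (0.046) and marginal zone genes (0.0156). The remaining lists did not pass: resting and quiescence (adjusted p = 0.219), S phase (0.218, and 0.0131 without wild type replicate 1), IL-4 response (0.801), NF-kB and TLR4 response (0.26), ribosome biogenesis and MYC targets (0.745), glycolysis (0.235), cholesterol synthesis (0.938), oxidative phosphorylation (0.776), MHC class II (0.203), calcium signalling (0.355), apoptosis (0.998), the KLF and SP family (0.639), the KChIP family (0.998) and sex-linked genes (0.92). In the IL-4 list the median (0.037) and the test's direction differed in sign, and apoptosis regulators had a mean of −0.018 with a median of 0.020.

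**Figure D2:**
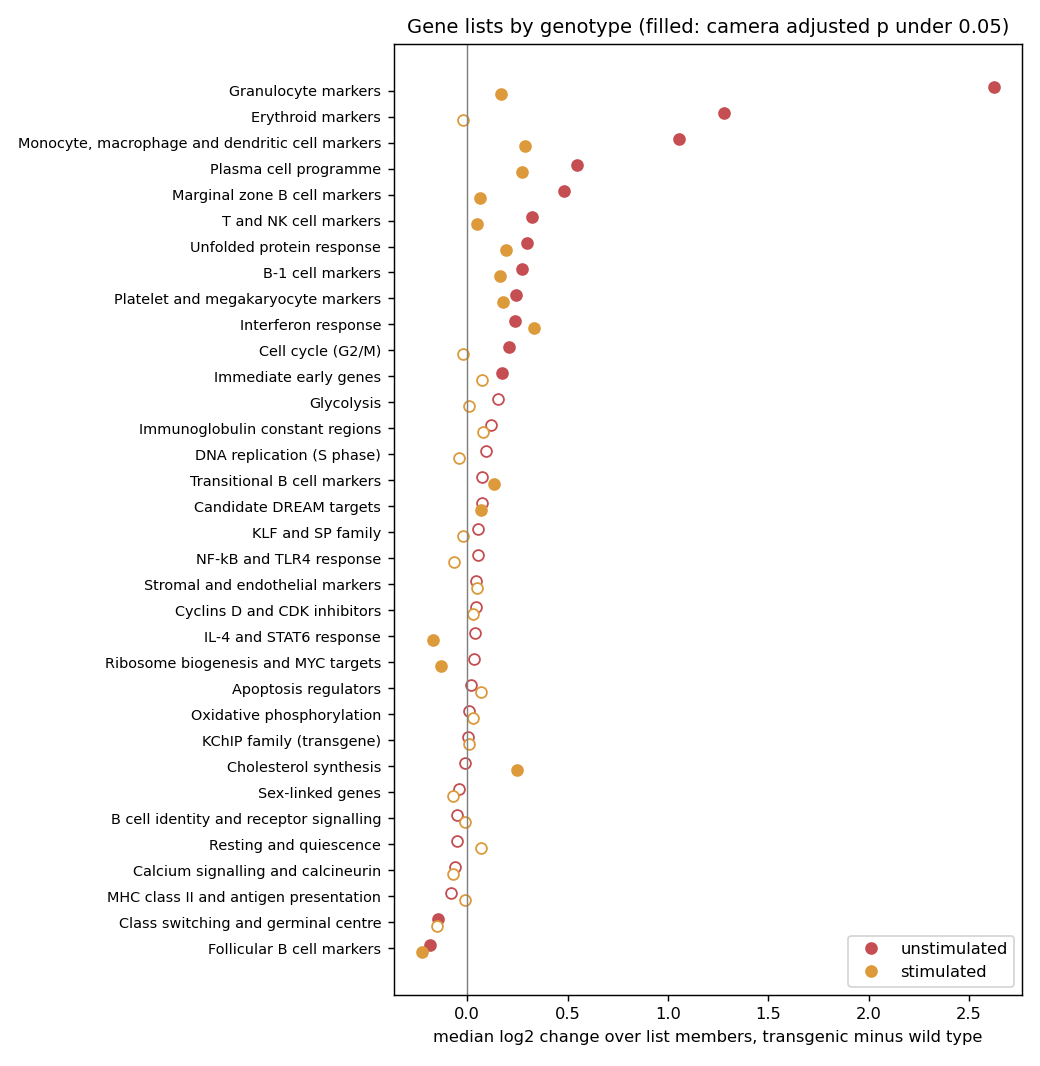
Median log2 change over the members of each gene list, transgenic minus wild type, in unstimulated (red) and stimulated cells (orange). Filled points passed the camera test; granulocyte markers had a median of 2.62 in unstimulated and 0.17 in stimulated cells.

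Stimulated transgenic and wild type cells were compared to see which differences between the genotypes were present 2 days after activation. Ctse was the most increased gene, at 6.15 ± 0.042 in wild type and 11.27 ± 0.11 in transgenic cells (5.12 ± 0.089, adjusted p = 4.45e-12), at 1 of its 2 probe sets. Plasma cell genes were again higher, with Jchain, which joins IgM and IgA into polymers, at 1.07 ± 0.12 and Prdm1 at 0.82 ± 0.15. Mndal was again the largest fall (−6.66 ± 0.19, adjusted p = 3.57e-10), followed by Ccnb1ip1 (−3.97 ± 0.095), a ubiquitin ligase of cyclin B, and Lad1 (−3.49 ± 0.15), an anchoring filament protein. Klf2 (−1.04 ± 0.078), a transcription factor of lymphocyte quiescence and homing, was lower too.

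Of 18 plasma cell genes 8 were higher and none lower in stimulated transgenic cells, 10 adjusted over the list alone (median 0.28, adjusted p = 4.86e-13), with Txndc5 (0.85 ± 0.14) and Tent5c (0.74 ± 0.14) beside Jchain and Prdm1. The calls of Prdm1 and Tent5c were each lost with some single arrays left out. Prdm1 changed by 0.77 without wild type replicate 3, and by 0.76 and 0.82 without transgenic replicates 1 and 2. Tent5c changed by 0.75 and 0.62 without wild type replicates 2 and 3, and by 0.70 without transgenic replicate 1 or 2. The unfolded protein response list had 5 higher of 23 and none lower, 7 adjusted over the list alone, among them Atf3 (0.65 ± 0.11) and Edem1 (0.63 ± 0.093) (adjusted p = 2.6e-09). Myeloid markers were higher in 4 of 21 cases, 8 adjusted over the list alone: the lysozymes Lyz1 (1.81 ± 0.31) and Lyz2 (1.34 ± 0.24), the scavenger receptor Marco (1.35 ± 0.16) and Cd14 (1.11 ± 0.20) (median 0.29, adjusted p = 7.48e-10). Without wild type stimulated replicate 3 the calls of Lyz2 (1.21) and Cd14 (1.07) were lost. Of 15 granulocyte markers 3 were higher, with S100a8 (1.74 ± 0.18) and S100a9 (1.16 ± 0.19) in front, also adjusted over the list alone. For granulocyte markers camera gave adjusted p = 0.000461, and adjusted p = 0.125 with an estimated correlation. No erythroid marker passed (adjusted p = 0.998). Of the 4 shared globin probe sets, which read several globin genes and did not enter the list test, 3 were higher by 1.41, 2.06 and 2.57 (adjusted p = 0.0147, 0.000125 and 0.000687). Of 9 platelet markers Pf4 (1.37 ± 0.18) was higher, with 1 other adjusted over the list alone (adjusted p = 0.00128).

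Other rises included the interferon-inducible genes Ifi202b (2.91 ± 0.13) and Ifi44l (2.69 ± 0.20), the acute phase gene Saa3 (2.43 ± 0.23), the chitinase-like Chil3 (3.32 ± 0.39) and Chil1 (1.92 ± 0.19), and Serpinb2 (1.84 ± 0.27). Clec4e (1.61) rose too, a call lost without wild type stimulated replicates 1 (1.55) or 3 (1.35) or transgenic stimulated replicates 2 (1.40) or 3 (1.62). Among the largest falls were Gbp2b (−2.89 ± 0.12), Gbp2 (−2.42 ± 0.11) and Gbp7 (−1.68 ± 0.14), which encode guanylate-binding proteins. In the interferon list of 20 genes 3 were higher and 1 lower, or 10 and 1 adjusted over the list alone, with Rsad2 (0.97 ± 0.15) and Bst2 (0.67 ± 0.13) among the higher and Gbp2 the lower. For interferon genes camera gave adjusted p = 1.65e-07, and adjusted p = 0.199 with an estimated correlation. Bst2 read 0.61, 0.65 and 0.53 without wild type replicates 1 and 3 and transgenic replicate 3, and did not pass. Slc15a2 (−2.88 ± 0.27), Golt1b (−1.97 ± 0.18), Ifi213 (−1.84 ± 0.20) and Tlr1 (−1.80 ± 0.10) were lower as they were in unstimulated cells.

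Klf3 (−1.21 ± 0.10) and Klf2 fell among 21 genes of resting and quiescent lymphocytes, and none rose (adjusted p = 0.781, with a median of 0.067 against a lower direction of the test); adjusted over the list alone 2 were higher and 3 lower. Klf3 fell at 1 of its 7 probe sets. The mean of the Klf3 probe sets changed by −0.33 and did not pass. In the KLF and SP family 3 of 18 were lower, 1 higher and 4 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.0676). It passed as lower after quantile normalization (adjusted p = 0.0384), and without wild type stimulated replicate 1 (0.00173) or transgenic stimulated replicate 3 (0.0280). Genes of the list of ribosome biogenesis and MYC targets were lower in 2 of 28 cases, 7 adjusted over the list alone, led by Polr1b (−0.92 ± 0.087), a subunit of RNA polymerase I. The list's median was −0.13, and camera gave adjusted p = 3.22e-07, and adjusted p = 0.167 with an estimated correlation. The IL-4 response list was lower, with Ccl22 (−0.67 ± 0.12) and Socs2 (−0.53 ± 0.11) lower of 21, or 2 higher and 5 lower adjusted over the list alone. For IL-4 response genes camera gave adjusted p = 0.00588, and adjusted p = 0.0517 with an estimated correlation. Both genes lost their calls when some single arrays were left out, between −0.60 and −0.56 for Ccl22 and between −0.50 and −0.45 for Socs2. No gene of cholesterol synthesis passed, 3 of 17 were higher adjusted over the list alone, and the list passed as higher. The median of the cholesterol list was 0.25, and camera gave adjusted p = 1.11e-06, and adjusted p = 0.0735 with an estimated correlation. Among immediate early genes Dusp2 (−1.16 ± 0.093) and Egr3 (−0.83 ± 0.12) were lower, and Dusp1 (0.82 ± 0.11) and Fos (0.74 ± 0.16) were among 4 higher of 22 (adjusted p = 0.218).

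Of 29 candidate DREAM targets Fos, Tg (0.58 ± 0.10) and Atf6 (0.57 ± 0.13) were higher in stimulated transgenic cells and none was lower, 3 and 1 adjusted over the list alone. For candidate DREAM targets camera gave adjusted p = 0.0458, and adjusted p = 0.167 with an estimated correlation. That call was lost without transgenic unstimulated replicate 1 (adjusted p = 0.0507), wild type stimulated replicates 1 (adjusted p = 0.0733) and 2 (adjusted p = 0.0834) and transgenic stimulated replicates 1 (adjusted p = 0.0675) and 3 (adjusted p = 0.0583), and after quantile normalization (adjusted p = 0.0635). Fos, Tg and Atf6 were not called in several such fits, at 0.59, 0.52 and 0.46 without transgenic stimulated replicate 1. The inhibitory receptor Fcgr2b (1.00 ± 0.083), the adaptor Pik3ap1 (0.86 ± 0.093) and the complement receptor Cr2 (0.53 ± 0.071) were higher of 26 genes of B cell identity and receptor signalling (adjusted p = 0.276). Marginal zone markers were higher in 4 of 16 cases, 6 adjusted over the list alone. For marginal zone markers camera gave adjusted p = 0.0116, and adjusted p = 0.135 with an estimated correlation. Transitional markers passed as higher with 1 of 12, Ly6d (1.02 ± 0.15). For transitional markers camera gave adjusted p = 0.0116, and adjusted p = 0.0735 with an estimated correlation. B-1 markers passed with 3 higher, such as Lgals1 (0.84 ± 0.087), and 1 lower, Cd300lf (−0.86 ± 0.13), of 13. For B-1 markers camera gave adjusted p = 0.00118, and adjusted p = 0.133 with an estimated correlation. Follicular markers passed as lower with Klf2 of 11. For follicular markers camera gave adjusted p = 0.000833, and adjusted p = 0.113 with an estimated correlation.

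Limma's moderated test passed 839 probe sets between the stimulated genotypes, 391 higher and 448 lower in transgenic cells, with 155 changed at least 2-fold (64 higher, 91 lower); as genes, 225 were higher and 200 lower. The genotypes' arrays did not overlap for 22.0% of the genes, against 10% by chance. The count was 551, 509 and 452 without wild type stimulated replicates 1, 2 and 3, 555 and 488 without transgenic stimulated replicates 1 and 2, and 1272 without wild type unstimulated replicate 1. Of 34 lists, 12 passed as higher and 3 as lower, and the calls of plasma cell (adjusted p = 0.0386), unfolded protein response (0.0347), myeloid (0.046) and platelet genes (0.046) held with an estimated correlation. Ccl5 (1.13 ± 0.12) was the 1 higher T or NK cell marker of 17. For T and NK cell markers camera gave adjusted p = 0.0433, and adjusted p = 0.405 with an estimated correlation. That list call was lost without wild type unstimulated replicate 3 (adjusted p = 0.0548), wild type stimulated replicates 2 (adjusted p = 0.0562) and 3 (adjusted p = 0.0828) and transgenic stimulated replicates 1 (adjusted p = 0.0535) and 3 (adjusted p = 0.129), and after quantile normalization (adjusted p = 0.0740). Class switching genes did not pass (adjusted p = 0.0505). They passed as lower with the replicate number as a block (adjusted p = 0.0435), and without wild type unstimulated replicates 1 (adjusted p = 0.0370) or 2 (0.0446), transgenic unstimulated replicate 3 (0.0482) or wild type stimulated replicate 1 (0.0259).

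**Figure D3:**
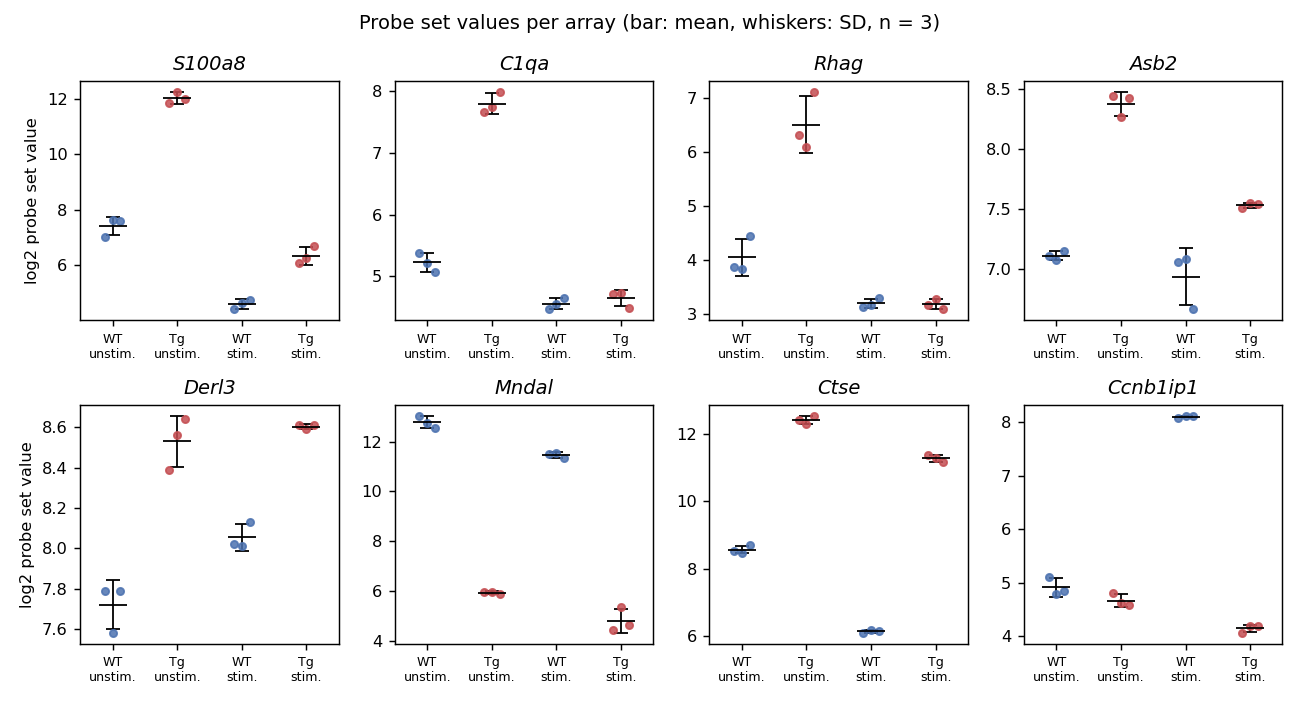
Log2 probe set values of 8 genes on each array of the 4 groups (wild type blue, transgenic red), with the mean as a bar and the SD as whiskers, n = 3. S100a8 had a mean of 12.03 in unstimulated transgenic and 7.41 in unstimulated wild type cells, and Mndal 5.94 and 12.79.

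The genotype differences before and after stimulation overlapped. They share no arrays, but they share each probe set's estimate of the spread. Replicates with the same number also resembled each other across the states in wild type cells. The counts expected from independent lists are therefore given for scale and are no test. As genes, 114 were higher in transgenic cells in both states, against 12.3 expected from independent lists of those sizes, and 81 were lower in both, against 9.81. Another 10 genes passed in both states in opposite directions. Across 18193 genes, which are not independent replicates, the changes in both states had a Pearson r of 0.43 and a Spearman rho of 0.27. A change of at least 2-fold in the same direction in both states was found for 31 genes, 19 higher and 12 lower, among them Ctse, Chil3, Chil1, Cd14, S100a8, Mndal, Slc15a2, Ifi213, Tlr1 and Golt1b. The overlap of 195 genes was 126 and 115 without wild type stimulated replicates 2 and 3, and 123 without transgenic stimulated replicate 2.

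Wild type cells kept 2 days with LPS and IL-4 were compared with unstimulated wild type cells of day 0. No cells kept 2 days without LPS and IL-4 were measured. Effects of stimulation and of time in culture can therefore not be told apart here, in either genotype. The deposited values gave a median change of −0.40 over all probe sets, and 29192 of 35555 called probe sets (82.1%) were lower. After quantile normalization over all 12 arrays that median change was 0.037, and 13813 of 25561 called probe sets were higher and 11748 lower (46.0%); with array medians subtracted it was 0.22, with 21383 of 30177 higher. Under all 3 scalings 3331 genes were higher and 2939 lower in wild type cells, of which 1320 and 845 by at least 2-fold. Changes and list counts in the next paragraphs are from the quantile-normalized values alone, and the members counted did not all move the same way in the deposited values. Camera's adjusted p is from the deposited values and, where the call differs, also from the normalized values. Camera's fits with an estimated correlation, a block or an array left out used the deposited values alone. The size of p can differ between the scalings in both directions. It was 0.0468 as deposited and 1.9e-05 after normalization for follicular markers, and 2.92e-14 and 4.6e-05 for oxidative phosphorylation.

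In wild type cells all 29 measured mitotic genes rose (median 3.37, adjusted p = 3.42e-28), including the spindle checkpoint kinase Bub1 (4.47 ± 0.24), Melk (4.22 ± 0.19), Hmmr (4.17 ± 0.091) and Aurkb (4.01 ± 0.089). DNA replication genes followed, with 29 of 31 higher and 1 lower (median 1.88, adjusted p = 5.71e-22), led by the licensing factor Cdc6 (4.28 ± 0.16) and Rrm2 (4.04 ± 0.13), a subunit of ribonucleotide reductase. Ccnd2 (3.40 ± 0.10) and the inhibitor Cdkn2b (3.23 ± 0.11) rose and the inhibitor Cdkn1b (−2.46 ± 0.12) fell, while the list of cyclins and inhibitors had 8 higher and 7 lower of 16 (adjusted p = 0.077). Myc (−1.25 ± 0.12) was lower at 2 days.

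Biosynthetic genes rose together in stimulated wild type cells. Of 28 genes of ribosome biogenesis or targets of MYC 27 were higher and none lower (median 1.53, adjusted p = 1.21e-22), among them the MYC targets Srm (3.44 ± 0.14), a spermidine synthase, and Hspd1 (2.28 ± 0.089), a mitochondrial chaperone. Cholesterol synthesis was higher in 16 of 17 cases (median 1.78, adjusted p = 1.08e-11), with Idi1 (3.97 ± 0.13), Fdps (3.32 ± 0.13) and Sqle (3.06 ± 0.13). Oxidative phosphorylation had 23 of 25 higher and 1 lower (adjusted p = 2.92e-14), for example Ndufv2 (1.30 ± 0.14), and glycolysis 12 of 14 higher and 1 lower, for example Tpi1 (2.50 ± 0.10) and the lactate carrier Slc16a1 (2.52 ± 0.14). For glycolysis camera gave adjusted p = 1.54e-07, and adjusted p = 0.095 with an estimated correlation. The fatty acid carrier Fabp5 (4.66 ± 0.17), the lipid phosphatase Plpp1 (4.93 ± 0.10) and the exonuclease Exo1 (4.63 ± 0.13) were among the 10 largest rises, as was the cytokine Il6 (4.60 ± 0.13). Interferon genes were higher in 14 of 20 cases and lower in 1 (12 and 5 as deposited), with Gbp2 (4.58 ± 0.11) and Ifit1 (3.97 ± 0.15). For interferon genes camera gave adjusted p = 8.11e-06, and adjusted p = 0.253 with an estimated correlation.

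Genes of the quiescence list and immediate early genes fell. Quiescence genes were lower in 19 of 21 cases and higher in 1 (median −1.96, adjusted p = 4.34e-06), led by Klf4 (−6.95 ± 0.12), the glucocorticoid-induced Tsc22d3 (−5.98 ± 0.11), the chemokine receptor Ccr7 (−4.16 ± 0.11) and Txnip (−3.86 ± 0.11). Immediate early genes were lower in 20 of 22 cases and higher in 2, none of which as deposited (median −2.38, adjusted p = 1.4e-06), with Fosb (−7.15 ± 0.10), Fos (−6.05 ± 0.15), the nuclear receptor Nr4a1 (−5.80 ± 0.10) and Dusp1 (−5.25 ± 0.10). Fosb, Fos, Nr4a1 and Junb are also among the 29 candidate DREAM targets, of which 12 were lower and 7 higher after normalization, and 24 lower and 1 higher as deposited. For candidate DREAM targets camera gave adjusted p = 0.00561, and adjusted p = 0.0735 with an estimated correlation. The KLF and SP family was lower in 13 of 18 cases and higher in 2 (17 and none as deposited), with Klf6 (−5.21 ± 0.10) and Klf9 (−2.77 ± 0.091) lower. For the KLF and SP family camera gave adjusted p = 0.000898, and adjusted p = 0.0686 with an estimated correlation. Rasgef1b (−7.37 ± 0.12), the regulators of G protein signalling Rgs2 (−6.06 ± 0.082) and Rgs1 (−5.15 ± 0.10), the lipid exporter Abca1 (−5.83 ± 0.12) and Plk2 (−5.30 ± 0.084) completed the 10 largest falls.

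B cell identity and receptor genes were lower in 21 of 26 cases and higher in none (median −1.07, adjusted p = 0.00244): Cr2 (−4.01 ± 0.069), the kinase Blk (−3.29 ± 0.072), Cd72 (−2.67 ± 0.093) and the transcription factor Ebf1 (−2.39 ± 0.11). Antigen presentation was lower in 9 of 15 cases and higher in 2, with H2-Oa (−2.79 ± 0.080), H2-Ob (−2.62 ± 0.093) and H2-Ab1 (−1.28 ± 0.12) lower and the costimulator Cd86 (1.33 ± 0.10) higher (adjusted p = 0.301 as deposited, 0.00169 after normalization). Of 21 IL-4 response genes 13 rose, including Ccl22 (4.28 ± 0.12), Cish (4.01 ± 0.086) and Socs2 (3.92 ± 0.10), and 6 fell, led by Gfi1 (−4.05 ± 0.17) (adjusted p = 0.000964 as deposited, 0.106 after normalization). Plasma cell genes went both ways, 8 higher and 5 lower of 18, with Xbp1 (1.23 ± 0.091), Prdm1 (1.53 ± 0.15) and Creld2 (1.65 ± 0.088) higher and Jchain (−2.26 ± 0.12) lower (adjusted p = 0.00828 as deposited with adjusted p = 0.317 with an estimated correlation, 0.448 after normalization). The call was likewise lost after normalization for the unfolded protein response (15 higher and 5 lower of 23, adjusted p = 1.38e-05 as deposited with adjusted p = 0.0735 with an estimated correlation, 0.16 after) and class switching genes (11 higher and 5 lower of 19, adjusted p = 0.0231 with adjusted p = 0.399 with an estimated correlation, 0.37 after), in which Exo1 and Batf (2.15 ± 0.12) rose and Bcl6 (−2.95 ± 0.11) fell.

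Igha (−1.65 ± 0.12) and Ighg3 (−1.36 ± 0.26) fell. Ighm had 4 probe sets higher and 5 lower of 11 in the deposited values, and its brightest probe set read −0.13 as deposited and 0.49 with medians subtracted. That probe set is the brightest on every array, so quantile normalization sets its change to 0, and no direction is given. Fcer2a likewise read −0.77 ± 0.11 after normalization but 0.18 with medians subtracted. The KChIP genes were not called after normalization except 1 that was higher, while 2 were lower as deposited. Kcnip3 read 0.27 ± 0.13 against −0.28 ± 0.12 as deposited (adjusted p = 0.0538; adjusted p = 0.0428 with the replicate number as a block). NF-kB and TLR4 response genes went both ways, 9 higher and 16 lower of 29, with Il6 higher and Ltb (−3.57 ± 0.16) lower; the deposited test was directed upward and the mean of −0.27 downward (adjusted p = 0.72). Calcium signalling genes fell in 14 of 23 cases and rose in 4, led by Orai2 (−2.47 ± 0.13). For calcium signalling camera gave adjusted p = 0.0426, and adjusted p = 0.113 with an estimated correlation. The calcium call was lost without wild type unstimulated replicate 2 (adjusted p = 0.0557). Apoptosis regulators did not pass, with 8 higher and 5 lower of 22 after normalization, and 9 higher and 12 lower as deposited (adjusted p = 0.162). Follicular markers fell in 9 of 11 cases, with Cd55 (−4.82 ± 0.068) and Icosl (−3.55 ± 0.12) (adjusted p = 0.0468; adjusted p = 0.296 with an estimated correlation; adjusted p = 0.0567 with the replicate number as a block). The follicular call was lost without wild type unstimulated replicate 2 (adjusted p = 0.0557) or 3 (0.0514), without any of the transgenic unstimulated arrays (0.051, 0.0533 and 0.0514) or without transgenic stimulated replicate 1 (0.0535). Transitional markers fell in 8 of 12 cases. For transitional markers camera gave adjusted p = 0.0326, and adjusted p = 0.113 with an estimated correlation.

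In wild type cells myeloid markers fell in 12 of 21 cases against 3 higher. For myeloid markers camera gave adjusted p = 0.0288, and adjusted p = 0.367 with an estimated correlation. Those that fell included Lyz1 (−4.52 ± 0.28) and Csf1r (−3.33 ± 0.18). Granulocyte markers fell in 9 of 15 cases (adjusted p = 0.0176; adjusted p = 0.253 with an estimated correlation). Erythroid markers fell in 8 of 12 cases against 1 higher. For erythroid markers camera gave adjusted p = 0.0426, and adjusted p = 0.462 with an estimated correlation. The lists of marginal zone (adjusted p = 0.301 as deposited, 0.00534 after normalization), B-1 (0.303), T and NK cell (0.235), platelet (0.162), stromal (0.178), immunoglobulin (0.378), KChIP (0.613) and sex-linked genes (0.816) did not pass as deposited. Of 34 lists 11 passed as higher and 11 as lower; 9 held with an estimated correlation: mitosis (adjusted p = 0.046), S phase (0.0315), ribosome biogenesis and MYC targets (0.0347), cholesterol synthesis (0.0347), oxidative phosphorylation (0.0156), the IL-4 response (0.0347), quiescence (0.0156), immediate early genes (0.0347) and B cell identity (0.0436). The arrays of the states did not overlap for 79.5% of the genes, against 10% by chance. Limma's moderated test called 9760 of the 35555 probe sets with at least 2-fold change in the deposited values.

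The same comparison in transgenic cells gave a response close to that of wild type cells: across genes the log2 changes had a Pearson r of 0.942, and 95.5% of the 12523 genes called in either genotype after normalization moved in the same direction. All 29 mitotic genes rose (median 3.23, adjusted p = 1.6e-28), for example Hmmr (4.06 ± 0.091), as did 29 of 31 replication genes (adjusted p = 6.11e-23), 27 of 28 genes of ribosome biogenesis and MYC targets (adjusted p = 1.65e-21) and 16 of 17 cholesterol genes (adjusted p = 3.69e-14). Quiescence genes fell in 19 of 21 cases (adjusted p = 4.42e-06), with Klf4 (−7.13 ± 0.12) and Klf2 (−4.12 ± 0.071), and immediate early genes in 20 of 22 (adjusted p = 1.96e-07), with Fosb (−7.39 ± 0.10) and Nr4a1 (−5.95 ± 0.10). The chemokine Cxcl3 (5.28 ± 0.32) and Il6 (4.70 ± 0.13) rose most together with Plpp1 (4.56 ± 0.10). S100a9 (−5.72 ± 0.18), S100a8 (−5.51 ± 0.18) and F13a1 (−6.10 ± 0.21), a coagulation factor subunit of monocytes and platelets, were among the 10 largest falls. Granulocyte markers fell in 14 of 15 cases. For granulocyte markers camera gave adjusted p = 1.62e-05, and adjusted p = 0.0735 with an estimated correlation. Erythroid markers fell in 11 of 12 cases (adjusted p = 0.000427; adjusted p = 0.215 with an estimated correlation) and myeloid markers in 16 of 21. For myeloid markers camera gave adjusted p = 0.000989, and adjusted p = 0.198 with an estimated correlation.

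In transgenic cells Ccnd2 (2.57 ± 0.10), Prdm1 (2.03 ± 0.15) and Xbp1 (0.67 ± 0.091) rose, and Jchain (−1.71 ± 0.12), Igha (−2.77 ± 0.12), Bcl6 (−2.83 ± 0.11) and Cr2 (−3.80 ± 0.069) fell. The plasma cell list had 9 higher and 6 lower of 18, and its deposited test (upward, adjusted p = 0.0147; adjusted p = 0.363 with an estimated correlation) differed in sign from its mean of −0.047 and was lost after normalization (adjusted p = 0.899). The NF-kB and TLR4 list had 10 higher and 17 lower of 29, with a median of −0.32, and passed as lower only after normalization (adjusted p = 0.951 as deposited, 0.0377 after). With all 12 arrays the same held for MHC class II (adjusted p = 0.429 as deposited, 0.00385 after), B-1 (0.203, 0.00931), T and NK cell (0.0687, 0.0231) and transitional markers (0.105, 0.0215). The T and NK cell list also passed camera as lower in the deposited values without transgenic unstimulated replicate 1 (adjusted p = 0.0496). Class switching (13 higher, 4 lower of 19), the IL-4 response (12 higher, 6 lower of 21) and the unfolded protein response (14 higher, 4 lower of 23) passed as higher in the deposited values and not after normalization. For class switching camera gave adjusted p = 0.00143 as deposited and 0.0558 after, and adjusted p = 0.253 with an estimated correlation. For the unfolded protein response it gave adjusted p = 1.29e-05 and 0.245, and adjusted p = 0.0735 with an estimated correlation, and for the IL-4 response adjusted p = 0.000906 and 0.126. Marginal zone markers fell in 12 of 16 cases, with Cd1d1 (−3.16 ± 0.12) and Dtx1 (−3.10 ± 0.090). For marginal zone markers camera gave adjusted p = 0.0449, and adjusted p = 0.215 with an estimated correlation. The marginal zone call was lost without any of the 3 wild type unstimulated arrays (adjusted p = 0.0505, 0.0527 and 0.0545). In the deposited values 29226 of 35407 called probe sets were lower (82.5%) and 9309 changed at least 2-fold; after quantile normalization 13556 were higher and 11284 lower of 24840, and with medians subtracted 22217 higher and 8104 lower of 30321. Under all 3 scalings 3223 genes were higher and 2721 lower, and the states' arrays did not overlap for 82.5% of the genes, against 10% by chance. Of 34 lists 11 passed as higher and 11 as lower in the deposited values, and 10 held with an estimated correlation: the 9 named for wild type cells and the KLF and SP family (adjusted p = 0.046).

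The interaction between genotype and state tested which genotype differences were unlike in unstimulated and stimulated cells, where stimulation and time in culture cannot be told apart. A negative value means that the difference, transgenic minus wild type, was lower in stimulated cells. The 5 most negative were S100a9 (−3.73 ± 0.27), Ccnb1ip1 (−3.72 ± 0.13), Ngp (−3.72 ± 0.25), Lad1 (−3.56 ± 0.21) and Camp (−3.41 ± 0.27). S100a9, Ngp and Camp were higher in unstimulated transgenic cells, and Ccnb1ip1 read 4.91 ± 0.18 and 8.11 ± 0.017 in unstimulated and stimulated wild type cells and 4.66 ± 0.12 and 4.14 ± 0.072 in transgenic cells. On the positive side stood Mdm1 (2.84 ± 0.17), Plk2 (2.31 ± 0.12) and Crisp3 (2.13 ± 0.14), lower in unstimulated transgenic cells, with Slc15a2 (2.01 ± 0.38) and Saa3 (1.91 ± 0.33). The call of Slc15a2 was lost without transgenic unstimulated replicate 2 (1.94) or wild type stimulated replicates 1 (1.95) or 2 (1.86).

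Among the lists, granulocyte markers were lower in 11 of 15 cases, 13 adjusted over the list alone (median −2.49, adjusted p = 1.53e-26), and erythroid markers in 8 of 12, also adjusted over the list alone (median −1.39, adjusted p = 3.18e-12). In stimulated wild type and transgenic cells the median levels were 4.63 and 5.01 for granulocyte and 4.75 and 4.71 for erythroid markers, below the array medians, so these sizes rest in part on dim probe sets. Marginal zone markers were lower in 4 of 16 cases, 7 adjusted over the list alone, with Marcks (−1.01 ± 0.15) and the cytokine subunit Ebi3 (−0.85 ± 0.12) in front (median −0.39, adjusted p = 8.45e-06). Myeloid markers were lower in 5 of 21 cases, with C1qa (−2.49 ± 0.15) and C1qb (−2.40 ± 0.15), and higher in 1, or 11 and 2 adjusted over the list alone. C1qa read 4.47 to 4.73 in the stimulated arrays of both genotypes, below the array medians, so its size rests in part on a dim probe set. The myeloid median levels in stimulated wild type and transgenic cells, 6.03 and 6.50, lay above the array medians. For myeloid markers camera gave adjusted p = 2.34e-07, and adjusted p = 0.0713 with an estimated correlation. Klf2 (−1.03 ± 0.11), Klf3 (−1.01 ± 0.15), Dusp2 (−1.29 ± 0.13), Polr1b (−0.80 ± 0.12) and Gbp2 (−1.82 ± 0.16) were lower, and Fcgr2b (0.87 ± 0.12) and the repressor Gfi1 (1.54 ± 0.24) higher. Igha (−0.96 ± 0.16), Prg2 (−2.18 ± 0.39) and Ccnd2 (−0.71 ± 0.11) were lower too, and Kcnip3 read −0.20 ± 0.18 (adjusted p = 0.683).

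Other lists passed with small shifts. Ribosome biogenesis and MYC targets (2 lower of 28, adjusted p = 7.95e-05; adjusted p = 0.253 with an estimated correlation) and mitotic genes (1 lower of 29, Ube2c, adjusted p = 0.00121; adjusted p = 0.474 with an estimated correlation) were lower, the latter not without wild type unstimulated replicate 3 (adjusted p = 0.171). Cholesterol synthesis was higher with no single gene called of 17. The median of the cholesterol list was 0.25, and camera gave adjusted p = 0.000647, and adjusted p = 0.177 with an estimated correlation. B cell identity genes (1 higher of 26, adjusted p = 0.0116; adjusted p = 0.0656 with an estimated correlation) and class switching genes (1 higher of 19, Hmces, adjusted p = 0.0197; adjusted p = 0.39 with an estimated correlation) were higher, the latter not without wild type unstimulated replicate 1 (adjusted p = 0.057). T and NK cell markers (no gene called of 17, adjusted p = 0.00969; adjusted p = 0.277 with an estimated correlation) and S phase genes (no gene called of 31, adjusted p = 0.043; adjusted p = 0.502 with an estimated correlation) were lower. Immediate early genes (1 lower of 22, adjusted p = 0.0426; adjusted p = 0.232 with an estimated correlation) and the KLF and SP family (5 lower of 18, adjusted p = 0.0326; adjusted p = 0.182 with an estimated correlation) were lower too. The S phase call was lost after quantile normalization (adjusted p = 0.0527). The S phase, immediate early and KLF calls were each lost without single arrays, at the most with adjusted p = 0.341 for S phase without wild type unstimulated replicate 3, 0.203 for immediate early genes without wild type unstimulated replicate 1 and 0.107 for the KLF family without wild type stimulated replicate 3.

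The interaction test passed 710 probe sets, 259 higher and 451 lower, with 253 changed at least 2-fold; as genes, 107 were higher and 253 lower. The count was 1418 without wild type unstimulated replicate 3, 407 without transgenic unstimulated replicate 3, 446, 388 and 419 without wild type stimulated replicates 1, 2 and 3, and 428 and 392 without transgenic stimulated replicates 1 and 2. Of 34 lists 3 passed as higher and 10 as lower, and granulocyte (adjusted p = 0.0113), marginal zone (0.0347) and erythroid markers (0.046) held with an estimated correlation.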

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

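The tests of marker lists, shared globins, gene order, the degraded array and the normalization were chosen only after their results were seen; the other splits of the arrays and the comparison of probe sets were planned. With 10 splits of 6 arrays a share under 0.05 cannot be reached. Each other split also keeps most arrays of a group in place and moves the real difference into the spread within groups. Low counts follow from that, so the other splits are no test of chance and give no rate of false calls. The real splits gave 4256 probe sets for the unstimulated genotypes (highest other split 1), 839 for the stimulated genotypes (highest other 0), 35555 for wild type stimulation (highest other 0) and 35407 for transgenic stimulation (highest other 0). Nor can it be reached with the 16 paired splits that keep 1 array of each replicate number in each group, which gave 710 probe sets for the interaction (highest other 423) and 38 list tests of both genotype contrasts and the interaction, adjusted over these contrasts alone (highest other 35). Without regard to the numbers, the highest others of 100 paired splits were 490 and 35. These highest values come from splits that keep the real grouping in 1 state; with both states regrouped the interaction called 0 probe sets and at most 23 list tests passed. For the overlap of both states (195 genes, highest other 0) the splits decide nothing, since the other splits of a state called at most 1 probe set.

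Differences between the states in the effect of genotype were found by the interaction test, and single arrays lying apart were not tested for in groups of 3. The effect was lower after stimulation for S100a9 (−3.73), Ccnb1ip1 (−3.72), Ngp (−3.72), Lad1 (−3.56), Camp (−3.41), Ltf (−3.06), Gbp2b (−3.01), S100a8 (−2.88), Slc40a1 (−2.67), Lcn2 (−2.49), Il1b (−1.89) and Gbp2 (−1.82). It was higher for Mdm1 (2.84), Plk2 (2.31), Crisp3 (2.13), Slc15a2 (2.01), Saa3 (1.91), Col6a4 (1.88), Ifi213 (1.74), Ifi44l (1.5), Ctse (1.28) and Tlr1 (0.80). As list means against all other genes, the differences were −2.02 for granulocyte, −1.19 for erythroid, −0.53 for myeloid, −0.36 for marginal zone and −0.29 for T and NK cell markers. They were −0.21 for the KLF and SP family, −0.19 for ribosome biogenesis and MYC targets, −0.19 for mitosis, −0.14 for immediate early genes and −0.11 for S phase, and 0.28 for cholesterol synthesis, 0.20 for class switching and 0.14 for B cell identity.

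Granulocyte, myeloid and erythroid markers were higher in unstimulated transgenic cells, whose CD43-depleted preparation has a stated purity above 98%. The median change of granulocyte markers exceeded that of T and NK cell markers by 2.30 (permutation p = 0.00025, 2-sided, genes reassigned between the lists). That p treats genes as independent and does not measure the spread between samples. The gap shows that the 2 lists did not change alike. A lower share of B cells would change them alike only if B cell signal and background were alike in both, which was not tested. In wild type cells 12 of 17 T and NK cell markers and 8 of 15 granulocyte markers lay above the array median. The gap therefore does not decide on an even rise of all other cell types. Nor can it decide on an uneven rise, since the depletion of CD43-positive cells need not remove all cell types to the same degree. Degraded RNA in wild type replicate 1 is argued against by a median change over the 3 lists of 1.07 without that array, beside 1.17 with it. RNA of myeloid and erythroid cells may be the source. The 4 shared globin probe sets were all higher, by a median of 1.43. They read alpha and beta globins, which the erythroid list also holds. They are therefore no separate support, and they do not bear on myeloid cells. Median levels went from 6.45 to 8.96 for granulocyte markers (brightest 12.03), from 6.73 to 7.92 for myeloid markers (brightest 13.3) and from 6.30 to 7.38 for erythroid markers (brightest 10.1). More such cells in the spleen of transgenic mice, and expression of these genes by the B cells, stay open and were not tested. A part of such RNA in the rises of the plasma cell and marginal zone lists was not tested either.

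The 31 genes changed at least 2-fold the same way by genotype in both states include Mndal, Ifi213, Ifi202b, Slc15a2 and Tlr1. Of these, 5 lay within 10 measured genes of another one, against a median of 0 in random sets (permutation p = 0.0124, 1-sided), among them Mndal, Ifi213 and Ifi202b in 1 stretch and S100a8 with S100a9 in another. Stretches of the genome that differ between the mice may explain some of these changes, and shared regulation of neighbouring family members stays open as well. Sequence differences under single probe sets cannot be told apart from changes in the transcript: another probe set disagreed for 78.6% of the genes with several (11 of 14) and for 49.3% (34 of 69) of genes changed in unstimulated cells alone (Fisher's exact p = 0.0753, 2-sided). Without wild type unstimulated replicate 1 all 31 genes were still called in both states, which argues against its RNA quality as the cause; the count was 23 without wild type stimulated replicate 3.

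Most stimulation calls were lower in the deposited values, 82.1% in wild type cells. Sorted values differed by 0.449 to 0.507 between states against at most 0.070 within a state. After quantile normalization over all arrays 46.0% were lower, but that step gives all arrays 1 distribution and moves the share whatever the cause. RMA's quantile normalization gives all arrays of 1 run near-equal distributions. The distances between the states therefore argue against 1 such run over all arrays. What normalization by state and biological differences each add to the share of lower calls cannot be told apart here.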

How the results depend on the processing

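All alternatives reported in this part were planned. The counts of 4256 (unstimulated genotypes), 839 (stimulated genotypes), 35555 and 35407 (stimulation in wild type and transgenic cells) and 710 (interaction) stayed within 1.5 times under both other scalings and the trended robust prior. They moved to 2001, 494, 14435, 14477 and 455 with the brightest probe set per gene, where fewer tests are made, and to 517, 155, 9760, 9309 and 253 with a change of at least 1. With the mean of probe sets they were 2003, 15268 and 15175 for the unstimulated genotypes and both stimulations, and 18004 and 18143 for the stimulations without dim probe sets. Array weights gave 8258, 1819 and 2189 for the genotype contrasts and the interaction, and a fit of only the groups compared, with fewer samples, gave 1908 for the unstimulated genotypes. List tests passed 86 times, and 31 times with an estimated correlation.

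With each array left out in turn the counts ranged from 2174 (without transgenic unstimulated replicate 3) to 7518 (without wild type unstimulated replicate 3) for the unstimulated genotypes, with 2611 without transgenic unstimulated replicate 1. They ranged from 452 to 1272 for the stimulated genotypes (without wild type stimulated replicates 1, 2 and 3: 551, 509 and 452; without transgenic stimulated replicates 1 and 2: 555 and 488; without wild type unstimulated replicate 1: 1272), from 33711 to 35480 and from 33195 to 36334 for stimulation in wild type and transgenic cells, and from 388 to 1418 for the interaction (without wild type unstimulated replicate 3: 1418; transgenic unstimulated replicate 3: 407; wild type stimulated replicates 1, 2 and 3: 446, 388 and 419; transgenic stimulated replicates 1 and 2: 428 and 392). The overlap of 195 genes ranged from 115 (without wild type stimulated replicate 3) to 222, with 126 and 123 without wild type and transgenic stimulated replicate 2, and list calls from 76 to 87. The cause was not tested. Summed over the 12 fits with an array left out, each call counted once per fit, 450 calls of named genes ended and 18 were added, and 46 list calls ended and 17 were added.

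Direction reversed for single genes, and the cause was not tested beyond the scaling itself. With the mean of probe sets Pik3cd (0.19), Cdca8 (−0.020) and Ccnd3 (−0.016) reversed between the unstimulated genotypes, Ighm with stimulation (0.62 wild type, 0.69 transgenic), Atp2a2 in wild type (−0.068) and Nid1 in the interaction (−0.028). With medians subtracted the stimulation changes of Kcnip3 (0.34 and 0.16), Ighm (0.49 and 0.47), Kcnip1 (0.030 and 0.17) and Kcnip4 (0.033 and 0.090) reversed in wild type and transgenic cells, of Fcer2a in wild type (0.18) and of Uty in transgenic cells (0.12). After quantile normalization Kcnip1 (0.0083 and 0.16) and Kcnip4 (0.024 and 0.064) reversed in both and Kcnip3 in transgenic cells (0.093); in wild type cells its sign changed too (0.27), with neither value called. The Ighm probe set, the brightest on every array, is set to a change of 0 by that step. The NF-kB and TLR4 list reversed with fry, which tests the mean against 0 (−0.27 wild type, −0.34 transgenic), and after quantile normalization in transgenic cells (−0.32).

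With the replicate number as a block the counts were 4966, 1000, 35724, 35582 and 767, list calls 86 and the overlap 241. The block ended the calls of Klf9, Nuf2 and Pfkm in unstimulated cells, of Usp18 and Rgs10 in stimulated cells, of Wdr12, Asb2, Cxcr5, Dntt and Pf4 in the interaction and of the follicular list in wild type stimulation, added those of Xist in unstimulated cells (−0.66), Kcnip3 in wild type stimulation (−0.28), Hmgcs1 (0.70) and Thy1 (−1.34) in the interaction and the class switching list in stimulated cells, and changed no other call of a named gene or list. Same-number r exceeded the others for replicates 2 and 3 alone in the unstimulated genotypes (0.078, 0.070 and 0.30) and for replicate 3 alone in transgenic stimulation (0.069, −0.16 and 0.12). An alternative for linear values was not run, since the values are log2. At 3 arrays per group the simulation recovered 53.7% of changes of 0.5, and what signal over background limits was not tested.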

Other observations

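Shared globin probe sets, which read several globin genes and did not enter the list tests, were bright in unstimulated cells and dimmer in stimulated cells. The beta globin probe set had a mean of 12.1 in wild type and 13.8 in transgenic unstimulated cells, and 7.91 and 9.32 after stimulation. Its change by genotype was 1.68 in unstimulated (adjusted p = 0.00167) and 1.41 in stimulated cells (adjusted p = 0.0147). The 3 alpha globin probe sets changed by 1.83, 1.17 and 1.18 in unstimulated cells (adjusted p = 0.000899, 0.00353 and 0.0342). In stimulated cells they changed by 1.00, 2.06 and 2.57 (adjusted p = 0.0874, 0.000125 and 0.000687).

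The Y-linked Eif2s3y read 3.33 to 3.78 in replicate 3 of each group and 8.27 to 9.55 in the other arrays, while the X-inactivation transcript Xist read 9.41 to 12.1 in all 12. The sex of the mice is not given in the sources used here. Hybridization controls averaged 8.96 in transgenic stimulated replicate 1 and 9.73 to 10.2 in the other arrays. The difference of the Gapdh probe sets, 5′ minus 3′ end, was −1.78 in wild type unstimulated replicate 1, against −0.38 to 0.020 in the other arrays, and its array weight was 0.289.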
